A study of Rattus norvegicus with 8 samples.

How the data were processed

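Total RNA of rat cardiomyocytes was hybridised to 8 one-colour microarrays, 4 of postnatal day 0 (P0) cells and 4 of postnatal day 10 (P10) cells. Per the labels, the RNA was isolated with the mirVana kit, dephosphorylated, denatured and labelled with the dye Cy3, and animals of either sex were used. The sample labels call the younger age P0, while the series title and design text call it day 1; the name P0 is used throughout and the conflict stays open. The array (Agilent design 031189) carries 1644 probes for 677 rat miRNAs on 13540 spots, beside 715 control spots. Groups and replicate numbers were taken from the sample labels.

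The deposited scanner files hold spot intensities. Per the file headers, they were written by Agilent Feature Extraction 10.7.1.1, and the processed signal used here is the spot's intensity minus a spatially detrended background of the same array, with no scaling between arrays, so values below 0 occur. The deposited spot table of the whole series holds the same intensities rounded to fewer digits, with a largest relative difference of 0.492% from the scanner files. It is therefore on a linear scale, uncentred, and runs in the same direction. The authors' deposited normalized matrix holds log2 values. Its normalization method is not given in the sources used here, but its detected values equalled a quantile normalization of the log2 of its own raw columns within 9.86e-07. Its 699 entries carry newer miRNA names, and 670 of the 677 miRNAs were matched by accession, 155 of the 158 tested ones among them. The deposited raw columns equalled the sum of each miRNA's own detected probes in 1423 of 1423 values compared, within 0.1%.

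All 8 arrays came from 1 slide and 1 scan, with P0 on the first row of the slide and P10 on the second, so the row of the slide and the age cannot be told apart and no slide block could be fitted. Array precision is limited by the number of arrays. No miRNA spot was saturated. A probe counted as detected on an array when at least 0.5 of its spots were well above background by the scanner's flag. Between 7.06% (P0 replicate 1) and 21.1% (P10 replicate 3) of probes were detected.

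The following choices were made before the data were examined, except where stated. Spots with an outlier mark were left out and the others of a probe averaged. Each array was divided by its 75th percentile over the 111 probes detected on all 8 arrays. A floor of 0.0169 on the scaled signal (log2 -5.89), the median over arrays of the lowest detected signal, was set after scaling, and log2 was taken. The probe with the highest mean stood for a miRNA with several probes. A miRNA was tested when it was detected on all 4 arrays of at least 1 age, which left 158 of 677. Differences are log2 P10 minus P0 from limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 158 miRNAs and a threshold of 0.05 on the adjusted p. Errors of differences are standard errors (SE), and errors of levels are standard deviations (SD). A miRNA not well above background on any array of 1 age has only a bound there, given as at least N-fold: the mean of the brighter age against the mean of, per P0 array, the higher of that array's lowest detected signal and the probe's own signal.

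The 21 lists of miRNAs were families and clusters known from heart and proliferating cells and markers of other cells a cardiomyocyte preparation can hold: miR-15, miR-17-92 and paralogs, let-7, miR-29, miR-30, muscle, miR-199a with miR-214, miR-34 with miR-449, miR-23/27/24, miR-181, miR-130 with miR-301, Dlk1-Dio3, miR-290 with miR-302, H19 and Igf2 hosted, and endothelial, smooth muscle, leukocyte, erythroid, neural, epithelial and liver markers. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted by Benjamini-Hochberg over 11 lists. The miRNAs named are up to 12 with the largest rise and 12 with the largest fall among those past the threshold with no overlap between the ages, up to 4 tested members of each list with the largest absolute difference, and miR-195, miR-1, miR-133a, miR-208, miR-208b and miR-499 wherever measured. This gave 7 rises, 7 falls, 51 list members and 5 single miRNAs, 59 different miRNAs in all. The number of miRNAs detected per array was compared with an exact two-sided permutation test over all 70 arrangements.

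The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Positions are those the scanner files give for the probes, on rat build rn4 (RGSCv3.4, per the file headers). Hairpin genes, their host genes and neighbours were named from a RefSeq gene table of GRCr8, which matched 49 of the 59 named miRNAs to 1 hairpin gene. That table carries no strand or exons, so a host is a gene whose span holds the hairpin. No genome sequence was used, and cross-hybridisation between near-identical family members was not measured.

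The test was tried on simulated data first. With 40 of 158 miRNAs changed in each of 20 rounds and 4 arrays per age, 53.8% of changes of log2 1 and 85.3% of changes of log2 2 were called in the right direction, and 4.14% of calls were of unchanged miRNAs. A miR-30 family lowered by log2 2 was called in 100% of 20 rounds, and 0.5% of other lists were called. The simulated noise was independent between miRNAs and between arrays and had no floor. Estimated correlations within the real lists ran from 0.329 to 0.978, and the P10 arrays lay in near-identical pairs. The simulated shares of recovered changes and of false calls may therefore not hold for the real arrays.

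Alternatives covered scaling, background correction by normexp with an offset of 50, the summary of probes, the authors' deposited values, the filter, the floor, the test, the replicate block and each array left out. In fits with arrays left out, the filter, the scaling probes, the floor and the choice of probe were set again on the arrays kept. Such fits therefore change the scaling as well as the arrays. Added after seeing the data were the fits without P10 replicates 1 and 2 or 3 and 4, with near-identical arrays averaged, with array weights estimated gene by gene, and with the sum of each miRNA's own probe totals. The files' total signal per miRNA was used only as an alternative: of 1445 detected values, 342 (23.7%) exceeded the sum of the miRNA's own detected probes by over 0.1%. The table work and figures used the package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.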

Results

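MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were measured in cardiomyocytes isolated from rats at P0 and at P10, with 4 arrays per age. The sample labels state that P10 cells proliferate less than P0 cells, and the comparison asks which miRNAs differ between the ages. Of 677 miRNAs on the array, 204 were detected on at least 1 array and 70 on all 8 arrays. The signal to which each array was scaled was 116, 1326, 806 and 1160 intensity units for P0 replicates 1 to 4 and 652, 580, 1276 and 1269 units for P10 replicates 1 to 4. P0 replicate 1 was thus the dimmest array, and its lowest detected signal lay at log2 -2.84 after scaling, against -6.61 to -5.48 on the others. The muscle miRNA miR-133b stood at log2 3.07 ± 0.21 (SD, n = 4) at P0 and 3.05 ± 0.68 at P10, and miR-1 at 2.57 ± 0.30 and 2.39 ± 0.52.

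With the 4 arrays per age counted as separate samples, 7 miRNAs were higher and 7 lower at P10. The P10 arrays lay in near-identical pairs, replicates 1 and 2 and replicates 3 and 4, and with each pair averaged 0 miRNAs passed the threshold. Age and the row of the slide cannot be told apart. The pair miR-497 and miR-195, members of the miR-15 family, rose 4.93-fold and 4.33-fold (log2 2.30 ± 0.29 and 2.12 ± 0.31, SE, n = 4 per age). miR-31 rose 12.1-fold (log2 3.59 ± 0.78), and miR-29a, of a family known for repressing collagen genes, 4.75-fold (2.25 ± 0.53). The endothelial miRNA miR-126 rose 4.49-fold (2.17 ± 0.43, or 1.54 ± 0.10 without P0 replicate 1 and rescaled). miR-146a, known from innate immune signalling, rose by log2 1.85 ± 0.48, and miR-208, the miRNA of the alpha myosin heavy chain gene, by 1.14 ± 0.25. Both lay at the floor on all 4 P0 arrays, so the floor sets the size of these differences. The hypoxia-induced miR-210 fell furthest among the 7 lower ones, with P0 at 4.26 times the P10 level (log2 -2.09 ± 0.34).

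Adjusted p-values from limma with Benjamini-Hochberg adjustment over 158 tested miRNAs were 0.00503 for miR-497, 0.00694 for miR-195, 0.0216 for miR-126, 0.0285 for both miR-208 and miR-31, 0.0404 for miR-29a and 0.0434 for miR-146a. In each of the 14 the 4 P0 and 4 P10 values, scaled and floored, did not overlap. P0 replicate 1, which detected nothing under -2.84, does not measure this for miR-497, miR-195, miR-208, miR-146a and miR-31, with all or some P10 values under that limit, nor for miR-484, which it did not detect. On P0 arrays, miR-208 and miR-146a lay at the floor on all 4, miR-31 on 3, miR-195 on 2 and miR-497 and miR-126 on 1, P0 replicate 1, so the folds of these 6 depend on the floor. With a doubled floor the log2 differences were 1.51 for miR-497, 1.21 for miR-195 and 1.92 for miR-126, still past the threshold, and 2.60 for miR-31, 0.89 for miR-146a and 0.25 for miR-208, which missed it. With no floor none of the 6 passed, as the errors grew (4.36 ± 1.92 for miR-497 and 4.27 ± 1.87 for miR-195). miR-208 and miR-146a were each detected on 1 P0 array, miR-31 and miR-195 on 2, and miR-497 and miR-126 on 3, while all 7 were detected on every P10 array. The second probe of miR-29a differed by 2.61. Those of the other 6 lay at the floor on every P0 array and could not have differed downward, so they do not test the direction. They differed by 2.57 for miR-31, 1.44 for miR-126, 0.55 for miR-146a, 0.31 for miR-195 and 0.07 for miR-497. That of miR-208 lay at the floor at both ages.

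**Figure D1:**
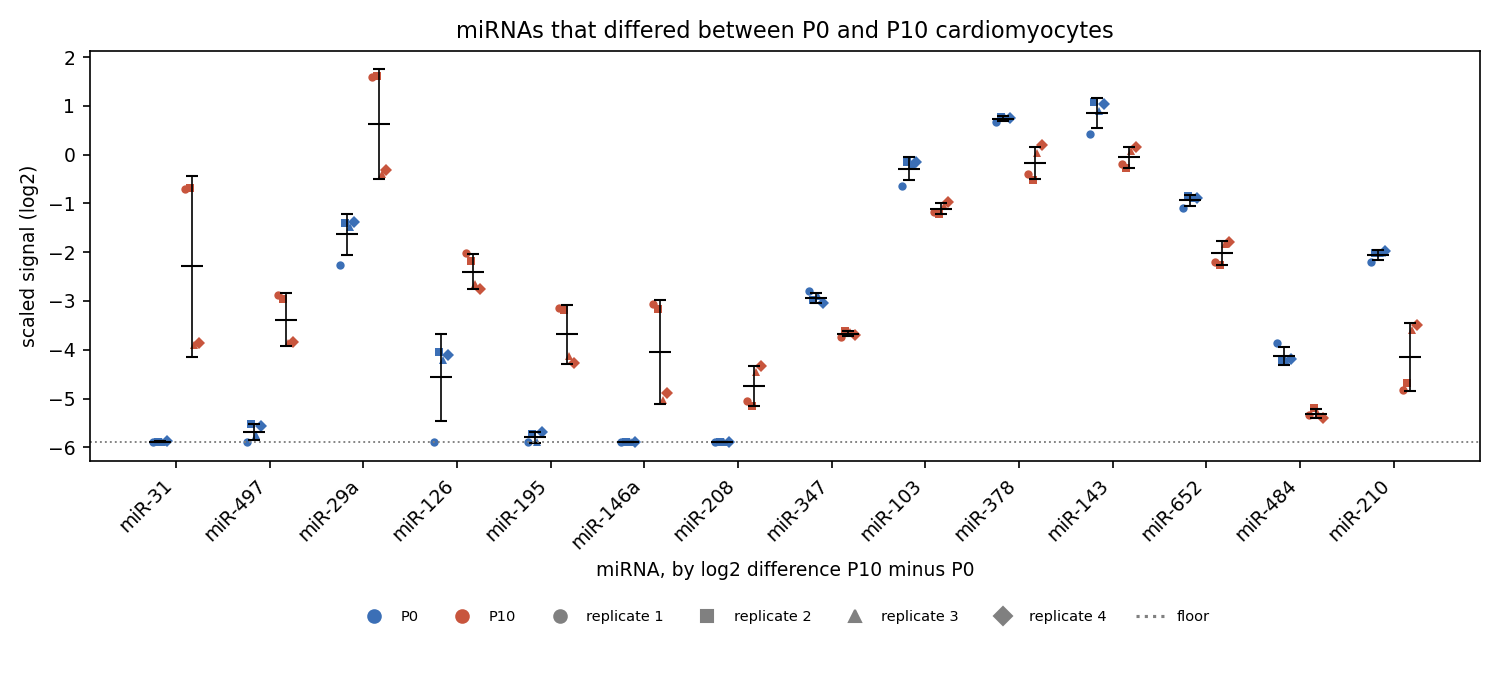
Scaled signal (log2, vertical axis) of the 14 miRNAs past the threshold at P0 (blue) and P10 (red), with a symbol per replicate, bars for the mean ± SD of 4 arrays and a dotted line at the floor of -5.89. P0 and P10 values as plotted do not overlap, with those of P0 replicate 1 under -2.84 being below what that array detected, and in all but miR-347 and miR-484 P10 replicates 1 and 2 stand apart from replicates 3 and 4, as for miR-31 at -0.70 and -0.69 against -3.91 and -3.87.

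Among the lower miRNAs, miR-484 fell by 1.19 ± 0.19 and miR-652 fell by 1.08 ± 0.21 on the log2 scale. The smooth muscle miRNA miR-143 fell by 0.92 ± 0.23, miR-378 fell by 0.91 ± 0.23, miR-103 fell by 0.82 ± 0.21 and miR-347 fell by 0.74 ± 0.18 (SE, n = 4 per age). With limma and Benjamini-Hochberg adjustment, adjusted p was 0.00797 for both miR-210 and miR-484, 0.0190 for miR-652 and 0.0434 for each of the other 4. Of the 7 lower miRNAs, 6 were detected on all 8 arrays and miR-484 on 7. Second probes differed the same way for 6 of the 7 (from -2.08 for miR-210 to -0.32 for miR-347), and that of miR-484 stayed at the floor at both ages.

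In rn4, the probes of miR-497 (chromosome 10, 57073850 to 57073868) and miR-195 (57074187 to 57074204) lie 337 bp apart. Those of miR-484 (826456 to 826471) and miR-146a (28476387 to 28476405) are on the same chromosome. The probe of miR-208 maps to chromosome 15 (33052009 to 33052023), and in GRCr8 its hairpin gene lies within the span of Myh6. miR-126 (chromosome 3, 4768167 to 4768183) lies within Egfl7, an endothelial gene, miR-652 (chromosome X, 35821380 to 35821394) within Tmem164, and miR-378 (chromosome 18, 57377854 to 57377866) within Ppargc1b, a coactivator gene of oxidative metabolism. miR-143 (chromosome 18, 57625176 to 57625193) lies within the non-coding gene Carmn, beside miR-145. The remaining probes map to chromosome 1 for miR-210 (201415728 to 201415742), chromosome 4 for miR-29a (58107816 to 58107834) and chromosome 5 for miR-31 (108497682 to 108497697), and miR-103 and miR-347 are given no single position by the scanner files.

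The size of this set depended on single arrays and on the scaling. In a fit without P0 replicate 1, the dim array, and with the scaling redone, the 7 higher and 7 lower miRNAs became 25 and 46, with 13 of the 14 kept. They became 3 and 2 without P0 replicate 2, 2 and 2 without P0 replicate 3, 3 and 2 without P0 replicate 4, 2 and 2 without P10 replicate 1, 3 and 2 without P10 replicate 2, 6 and 3 without P10 replicate 3 and 11 and 7 without P10 replicate 4. With no scaling between arrays, 11 were higher and 0 lower, and the median difference of all tested miRNAs moved from 0.03 to 0.35. All 14 kept their sign under quantile scaling, median scaling and no scaling. P10 replicates 1 and 2 were near-identical, as were 3 and 4. When each pair was averaged, an alternative added after seeing the data, limma called 0 higher and 0 lower, with 26 of 158 at an unadjusted p under 0.05 against 44 before. Without P10 replicates 3 and 4, 50 were higher and 26 lower, with all 14 kept. Without P10 replicates 1 and 2, 6 were higher and 8 lower, with 10 of the 14 kept. Both fits leave 1 near-identical pair at P10, possibly of the same RNA, so its small spread may not be that between separate samples. Of the 45 other tested miRNAs named here, the log2 difference turned sign in 5 and otherwise moved by over 1.5 times in 23 without P0 replicate 1. Without P10 replicates 1 and 2 these counts were 9 and 33. Their single values below thus depend on those arrays or on the scaling redone without them, which these fits do not separate. The sizes of the 14 moved as well. Over all alternatives the log2 difference ranged, for example, from 1.23 to 5.73 for miR-31, 1.27 to 3.21 for miR-29a and 0.14 to 4.88 for miR-146a.

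Some values also depended on how the signal was read. After normexp background correction 0 miRNAs passed, with differences of 0.41 ± 0.52 for miR-497, 0.28 ± 0.52 for miR-195 and -0.07 ± 0.46 for miR-208, and miR-484 had a difference of 0.22 in the authors' deposited log2 matrix. With the files' total signal per miRNA, which in 342 of 1445 detected values also contains the preceding miRNA's total, miR-497 had -0.23, miR-195 -1.31 and miR-484 1.02.

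Markers of cells other than cardiomyocytes moved in both directions with age. The endothelial miR-126 rose and the smooth muscle miR-143 fell, as given above, and its neighbour miR-145 differed by -0.69 ± 0.37 (SE, n = 4 per age; adjusted p = 0.250, limma with Benjamini-Hochberg), or by -1.18 ± 0.40 without P0 replicate 1 (adjusted p = 0.0518 in that limma fit). Of the leukocyte list, 1 of 2 tested members rose, miR-146a, and miR-223, abundant in myeloid cells, differed by -0.24 ± 0.69 (adjusted p = 0.836 in the same limma fit). Adjusted over the list alone, the same 1 of 1 endothelial, 1 of 2 smooth muscle and 1 of 2 leukocyte members passed. Within P10, miR-126 was 0.48 to 0.73 and miR-146a 1.73 to 1.95 higher (log2) on replicates 1 and 2 than on 3 and 4, and miR-145 differed by -0.93 to -0.70. miR-128, the tested neural marker, differed by 0.26 ± 0.44 and by -0.40 without P0 replicate 1, where miR-223 turned to 0.28. The erythroid list (2 members on the array), the epithelial list (6) and the liver list (3) had 0 tested members.

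Heart and skeletal muscle miRNAs did not move together. Of 6 tested muscle miRNAs, 1 rose, miR-208, also when adjusted over the list alone. miR-1 differed by -0.18 ± 0.30 and miR-133a by -0.50 ± 0.38 (SE, n = 4 per age), with adjusted p of 0.697 and 0.390 by limma with Benjamini-Hochberg. Without P0 replicate 1 they stood at -0.51 and -0.78, and without P10 replicates 1 and 2 at 0.27 and 0.17. miR-499, which lies within the myosin gene Myh7b, differed by -0.75 ± 0.39 (adjusted p = 0.236, limma), and miR-206, at 1.05 ± 0.45, was detected on 1 P0 array and lay at the floor on 2 (adjusted p = 0.158, limma). miR-208b-3p, the form of miR-208b on the array, was detected on 2 arrays of each age and was not tested. The list's median was -0.10 and its mean 0.12, and camera gave a direction up with an adjusted p of 0.859 after Benjamini-Hochberg. The median turned to 0.42 with no scaling and to 0.41 without P10 replicates 1 and 2.

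Of 5 tested members of the miR-15 family, 2 rose, miR-497 and miR-195, while miR-16 differed by 0.16 ± 0.25 (-0.16 without P0 replicate 1) and miR-322 by -0.23 ± 0.39. The family's median of 0.16 turned to -0.16 without P0 replicate 1 and to -0.10 without P10 replicates 1 and 2. Of 3 members of the miR-29 family, 1 rose over all miRNAs and 2 adjusted over the list alone: miR-29a and miR-29b (1.85 ± 0.58), beside miR-29c at 0.53 ± 0.29. All 3 members of the list of miR-199a with miR-214, whose hairpins lie within Dnm3, passed adjusted over the list alone and none over all miRNAs: miR-199a-3p at 2.57 ± 0.86, miR-199a-5p at 2.23 ± 0.81 and miR-214 at 2.17 ± 0.85. Their mean level was -0.38 and -0.36 on P10 replicates 1 and 2 but -3.71 and -3.77 on replicates 3 and 4, against -4.85 to -4.20 on the P0 arrays. In the miR-23/27/24 clusters, 1 of 5 passed adjusted over the list alone, miR-23a (1.31 ± 0.35), and 0 over all; miR-27a stood at 0.93 ± 0.37, miR-24 at 0.41 ± 0.26 and miR-23b at 0.03 ± 0.23. Without P0 replicate 1 these 3 became 0.59, 0.11 and -0.28.

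On the lower side, 2 of 3 tested members of the family of miR-130 with miR-301 passed adjusted over the list alone and 0 over all: miR-130b at -1.44 ± 0.41 and miR-301a at -1.10 ± 0.32, beside miR-130a at -0.31 ± 0.21. In the miR-181 family 1 of 4 passed adjusted over the list alone, miR-181b (-0.62 ± 0.19), and 0 over all; miR-181a stood at -0.54 ± 0.24, miR-181d at -0.24 ± 0.25 and miR-181c, at the floor on P0 replicate 1, at 0.62 ± 0.37. Without that array miR-181d became -0.54 and miR-181c 0.10. Of 5 tested members of the miR-30 family 0 passed on either basis, and all 5 differences were negative, from -0.71 ± 0.27 for miR-30b-5p to -0.26 ± 0.30 for miR-30a. The family's median of -0.51 became 0.01 with no scaling, where 3 of the 5 were positive, -0.09 without P10 replicates 1 and 2, where 2 were, and -0.82 without P0 replicate 1. miR-30d (-0.69), miR-30c (-0.51) and miR-30e (-0.43) lay between.

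Of the 11 lists tested, camera at the preset correlation called 0 after Benjamini-Hochberg adjustment, and 5 shared the lowest adjusted p of 0.0851: miR-15, miR-29 and miR-199a with miR-214 (up), and miR-30 and miR-130 with miR-301 (down). With an estimated correlation the lowest adjusted p was 0.794, and fry gave a lowest adjusted p of 0.112. Unadjusted, those 5 lists had camera p of 0.0387, 0.0191, 0.0268, 0.0319 and 0.0202 in that order. The medians of miR-29 (1.85), miR-199a with miR-214 (2.23) and miR-130 with miR-301 (-1.10) became 0.72, 0.61 and -0.59 without P10 replicates 1 and 2, where those of miR-15 and miR-30 came to -0.10 and -0.09. That of miR-199a with miR-214 became 1.105 after normexp, and that of miR-130 with miR-301 -0.58 with no scaling. The number of lists called was 4 without P10 replicate 3 and 4 without both P10 replicates 3 and 4, was 1 without P10 replicates 1 and 2, and was 0 without any other single array.

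**Figure D2:**
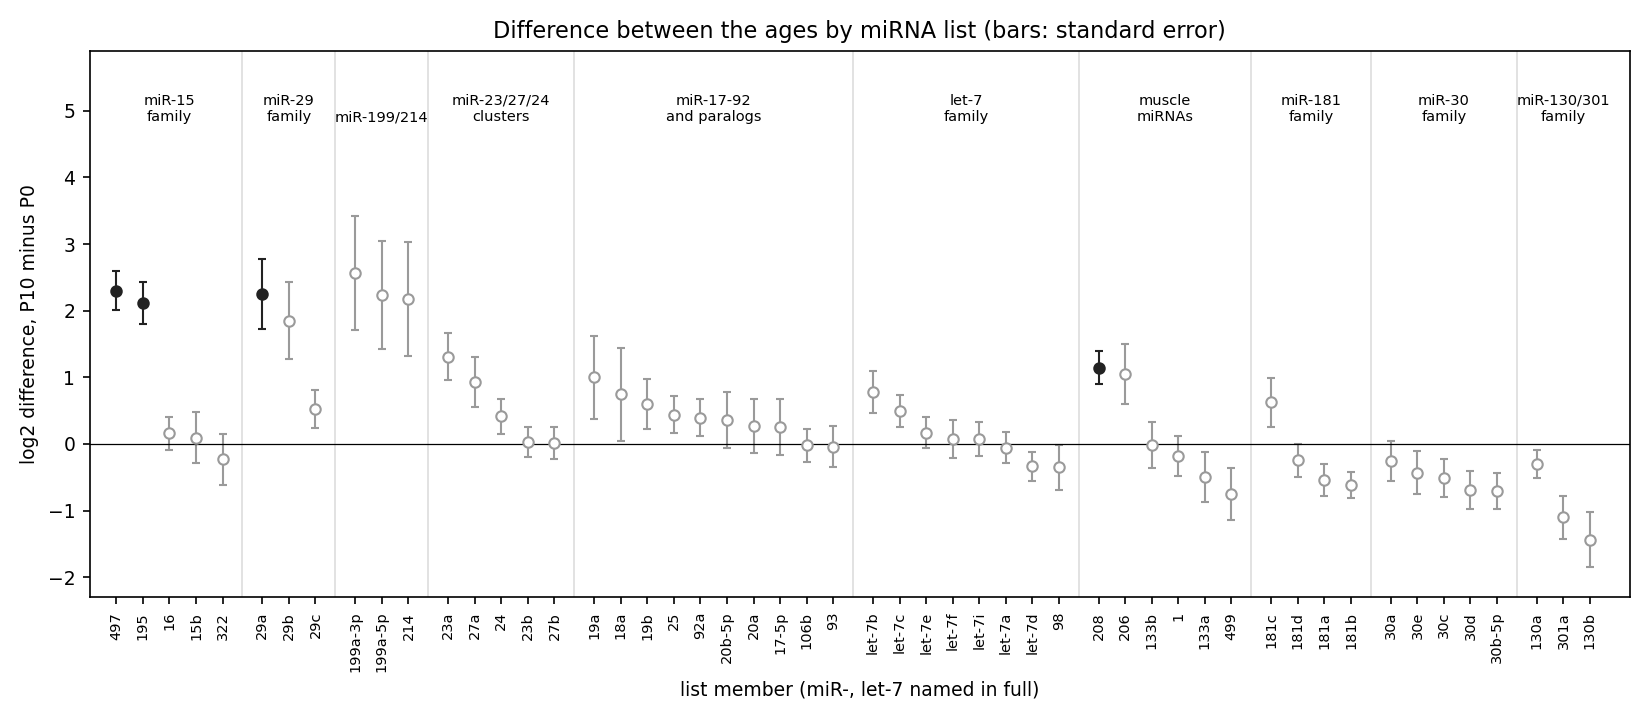
Log2 difference P10 minus P0 (vertical axis) with its SE for each tested member of 10 lists (n = 4 arrays per age), filled where the adjusted p over all miRNAs was under 0.05. Filled points are miR-497, miR-195, miR-29a and miR-208, and the differences of the miR-30 family, all below 0 here, have a median of 0.01 when arrays are not scaled.

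The lists of miR-17-92, let-7, Dlk1-Dio3, miR-34 with miR-449, miR-290 with miR-302 and H19 with Igf2 held 0 miRNAs past the threshold, over all or adjusted over the list alone. Of 10 tested members of miR-17-92 and its paralogs, a group known for promoting cell division, 8 differences were positive, led by miR-19a (1.00 ± 0.62), miR-18a (0.74 ± 0.70), miR-19b (0.60 ± 0.37) and miR-25 (0.44 ± 0.28). Without P0 replicate 1 and rescaled, miR-19a stood at 0.34, miR-18a at 0.12, miR-19b at 0.22 and miR-25 at 0.06. In that fit 5 of the 10 were positive, with a median of -0.01. The median of 0.38 turned to -0.28 without P10 replicates 1 and 2, and camera's adjusted p was 0.256. Of 8 let-7 members, 5 were positive (let-7b 0.77 ± 0.32, let-7c 0.50 ± 0.24, let-7d -0.34 ± 0.22, miR-98 -0.35 ± 0.34), with a median of 0.07 that turned to -0.20 under quantile scaling and a camera adjusted p of 0.859. The miR-23/27/24 and miR-181 lists had camera adjusted p of 0.211 and 0.308, and the 6 tested members of the imprinted Dlk1-Dio3 cluster 0.916. In that cluster the star strand of miR-770 differed by -0.47 ± 0.26 and miR-409-3p by -0.39 ± 0.65, or 0.11 without P0 replicate 1. miR-134 lay at the floor on all P0 arrays, so its difference of 0.39 ± 0.24 is set by the floor and ranged from -0.27 to 4.97 over the alternatives. miR-539 was not well above background on any P0 array and was at least 1.11-fold higher at P10 (adjusted p = 0.221, limma with Benjamini-Hochberg). The cluster's median of -0.17 turned to 0.35 with no scaling. Too small to test as lists were miR-34 with miR-449 (miR-34a 0.53 ± 0.36), miR-290 with miR-302 (miR-290 -0.36 ± 0.33 and miR-295 -0.12 ± 0.26, both above 0 with no scaling) and the H19 and Igf2 hosted list (star strand of miR-483, 0.27 ± 0.31).

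The repertoire of detected miRNAs did not differ past the threshold. P0 arrays detected 73, 176, 157 and 158 miRNAs (141 ± 46.2, SD, n = 4) and P10 arrays 171, 170, 187 and 169 (174 ± 8.54), a difference of 33.3 with an exact two-sided permutation p of 0.114, where 70 arrangements allow no p below 0.0286. The difference was 10.6 without P0 replicate 1 (exact permutation p = 0.229) and 44.9 without P0 replicate 2 (exact permutation p = 0.0286).

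Levels of the 158 miRNAs grouped the arrays partly across age. P10 replicates 1 and 2 correlated at r = 0.998 and P10 replicates 3 and 4 at 0.997, over miRNAs, which are not independent replicates, while the r between those pairs was 0.890 to 0.898. P10 replicates 3 and 4 correlated more with P0 replicates 2 to 4 (0.929 to 0.958) than with P10 replicates 1 and 2. P0 replicates 2 to 4 correlated among themselves at 0.979 to 0.994 and with P0 replicate 1 at 0.808 to 0.884.

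**Figure D3:**
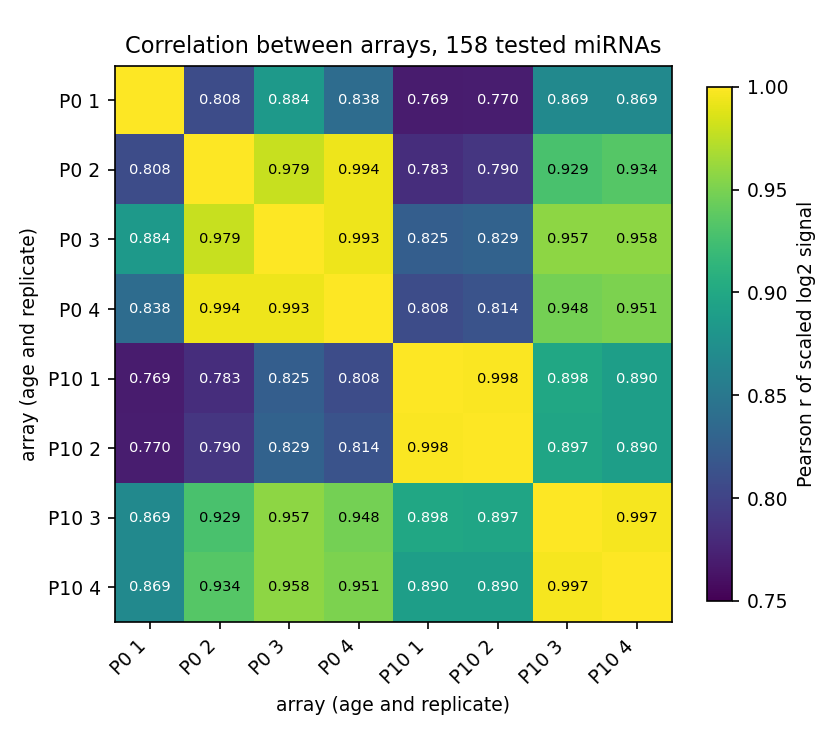
Pearson correlation (colour and printed value) of scaled log2 signals over the 158 tested miRNAs between each pair of the 8 arrays, named on both axes by age and replicate. P10 replicates 1 and 2 (0.998) and 3 and 4 (0.997) form pairs, and P0 replicate 1 has no correlation above 0.884.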

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

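Of the tests in this part, those on P0 replicate 1, on repeat hybridisation, on the share of cardiomyocytes and on the files' total signal were chosen only after the result was seen, while the splits of the arrays and the brightness test were set beforehand.

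P0 replicate 1 was the lone far value among the 4 P0 arrays for 27 of 59 named miRNAs. In all, 29 of 122 groups of 4 values held a sample set far from the others (a gap above Dixon's 95% critical value), where chance gives about 1 in 20. On that array 24 miRNAs lay below the other P0 arrays, in scaled log2 units: miR-126 and miR-181c at the floor of -5.89, miR-128 at -5.81, miR-19a at -5.69, miR-18a at -5.33, miR-145 at -5.06, miR-199a-3p at -4.60, miR-181d at -4.38, miR-29c at -3.98 and miR-181b at -3.86. Also below were miR-322 at -2.68, miR-25 at -2.60, miR-130b at -2.38, miR-29b at -2.28, miR-29a at -2.26, miR-210 at -2.20, miR-34a at -1.61, miR-19b at -1.14, miR-301a at -0.92 and miR-103 at -0.64. In addition, miR-16 stood at 0.26, miR-24 at 0.28, let-7d at 0.84 and miR-1 at 2.13, also below the others. Above the other P0 arrays lay miR-484 at -3.85, the star strand of miR-483 at -2.46 and miR-539 at -5.31. Values under -2.84, the lowest detected signal of that array, were not above its background, so the exact place of those miRNAs there, above or below, means little.

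A failed labelling or hybridisation of P0 replicate 1 was argued against by its spike-in controls. Its labelling spike-in was 3.93 in log10 units, 0.0510 above the mean of the other 7 arrays (3.84 to 3.91), and its hybridisation spike-in of 4.46 lay within their range of 4.41 to 4.53. Less of the same RNA, lowering every miRNA by 1 factor, was argued against too, since the variance of its log2 differences from each other P0 array was at least 130 times that expected from spots, against 4.31 to 16.2 among P0 replicates 2 to 4. A P10 sample under a P0 label cannot be told apart from a P0 sample: 11 of 27 miRNAs (40.7%) lay nearer the P0 than the P10 mean, and no bound set for the test was met. An earlier form of this test, correlation over 70 miRNAs, met its own criterion for a P10 sample, with r of 0.8515 with P10 replicate 4 against 0.8506 with P0 replicate 3, and was set aside after that result as too close to decide. Degraded or otherwise different RNA may remain as a cause, and no biological explanation was tested.

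P10 replicates 1 and 2 differed from each other by an SD of 0.136 in log2 and replicates 3 and 4 by 0.204, against 0.974 to 1.03 between the pairs. Brightness as the cause was argued against, since the difference between P10 replicates 1 and 3 followed that between a dimmer and a brighter P0 array only at r = 0.194 over miRNAs. A lower share of cardiomyocytes on replicates 1 and 2, with all other cells alike, was argued against only by miR-145 and miR-143. These are neighbours among 4 markers of other cells chosen for this test, which no other list holds. miR-126 and miR-146a were higher there. miR-145, however, differed by -0.93 to -0.70 and miR-143 by -0.43 to -0.28, with an SD within pairs of up to 0.204. Outside the 4, miR-223 was higher on replicates 1 and 2 (-4.19 and -4.08 against -5.40 and -5.43). miR-128 was lower there (-4.14 and -4.31 against -3.99 on both others). The list of miR-199a with miR-214 was higher there (mean -0.38 and -0.36 against -3.71 and -3.77). A lower share with a different mix of other cells was not excluded. The muscle miRNA miR-1 stood at 1.98 and 1.90 on replicates 1 and 2 against 2.85 and 2.82 on 3 and 4. miR-133b stood at 2.54 and 2.39 against 3.58 and 3.69. miR-133a, miR-499 and miR-208 were lower there too, while miR-206 was higher. Repeat hybridisations of the same RNA cannot be told apart from separate samples. The variance within the pairs was 4.75 (replicates 1 and 2) and 11.05 (3 and 4) times that expected from spots. Both lay within the range of 4.31 to 16.2 among P0 replicates 2 to 4, which may themselves be repeats. More cells of 1 other type on replicates 1 and 2 may also account for the pairs, and whether cardiomyocytes themselves express these markers was not measured.

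The files' total signal per miRNA turned the sign of miR-497, miR-195 and miR-484. In 342 of 342 values above the sum of the miRNA's own probes, the excess equalled the total of the preceding detected miRNA in name order, within 0.1%, so the column holds a running total for part of the miRNAs. At least 1 such value was found for 56 tested miRNAs, 9 of them past the threshold, and why the column was written so stays unknown.

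With all 8 arrays counted as separate samples, chance was argued against for the count of miRNAs. Of the 35 splits into 4 and 4, only 1, the real one, gave as many as 14, and the highest other gave 0. A share under 1 of 35 was not possible. The real split is also that of the slide's rows, so it does not separate age from row. The splits would not argue against chance if arrays were not separate samples, such as the P10 pairs or P0 replicates 2 to 4. Repeats of the same RNA would be 1 such case. With each P10 pair averaged 0 miRNAs were called, and with P0 replicates 2 to 4 averaged as well 1 was. For the lists the splits tested nothing: with 0 lists called between the ages, 35 of 35 splits had to call at least as many. The highest other called 8, setting P0 replicates 1 to 3 and P10 replicate 4 against the other 4 arrays, which points to some structure among the arrays. Every split that called more than 1 list kept P10 replicates 1 and 2 on the same side. The real split and some others also kept them together but called 0, and the cause was not tested. On P0 replicate 4, miR-31 stood at -5.87 while the other 3 P0 arrays were at the floor. P10 replicate 3 had 187 detected miRNAs, far from the 169 to 171 of the other P10 arrays.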

How the results depend on the processing

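The fits with arrays averaged or weighted, with P10 pairs left out and with each miRNA's own probe totals were chosen only after the result was seen. Over all alternatives, the 14 miRNAs past the threshold gave 412 values: 210 stayed past it in the same direction, 197 missed it in the same direction and 5 missed it with the other sign. The 45 other named miRNAs gave 1331 values: 1251 stayed below the threshold, 79 of them with the other sign, a further 79 passed it in the same direction, and 1 passed it with the other sign (miR-23b without P0 replicate 1). Against 7 higher and 7 lower miRNAs and 0 lists, counts were as follows, and the cause was not tested except where stated. No scaling gave 11 higher and 0 lower, 4 of them among the 14 (27 at an unadjusted p under 0.05 in limma), as did the unscaled deposited spot values, 11 and 0. Normexp gave 0 higher and 0 lower (22 unadjusted) with 4 lists, and miR-208 at -0.072. The mean over all probes gave 4 and 4. The files' total signal gave 0 and 0 (32 unadjusted), with miR-497 at -0.23, miR-195 at -1.31 and miR-484 at 1.02, a column that holds running totals, while the sum of each miRNA's own probe totals gave 11 and 2. The authors' log2 matrix gave 1 and 1, 0 of them among the 14, with miR-484 at 0.22. No filter (677 tested) gave 1 and 3 with 10 lists, detection on all 8 arrays (70 tested) 2 higher and 10 lower, detection on at least 1 array (204 tested) 6 and 14. A doubled floor gave 5 and 15, a halved floor 9 and 7, and no floor 1 and 3. Quantile scaling gave 9 and 8, median scaling 9 and 6, and eBayes with trend and robust 8 and 7, all within 1.5 times. Leaving out P10 replicates 3 and 4 gave 50 and 26 with 4 lists. Leaving out 1 and 2 gave 6 and 8 with 1 list, and both fits leave 1 near-identical pair at P10. Averaging each P10 pair gave 0 and 0 (26 unadjusted), and averaging P0 replicates 2 to 4 as well gave 1 (miR-31) and 0 with 2 lists; fewer samples entered both. Array weights gave 33 and 41. Leaving out each array in turn, with the scaling redone, gave 2 to 25 higher, 2 to 46 lower and 0 to 4 lists. The 25 and 46 were without P0 replicate 1. miR-23b ranged from -0.28 without P0 replicate 1 to 0.10 without P10 replicate 4. The difference in detected miRNAs ranged from 10.6 without P0 replicate 1 to 44.9 without P0 replicate 2, where it passed (exact permutation p = 0.0286), and was 31.5 with all spots required and 39.3 with the files' flag. The replicate block gave 3 higher (miR-31, miR-497 and miR-195) and 1 lower (miR-210). Whether equal numbers mark paired arrays cannot be told. Deviations of same-numbered arrays correlated only at 0.163, -0.154, 0.033 and 0.136. P0 replicates 1, 3 and 4 correlated best with their own number, by small margins, and P0 replicate 2 with P10 replicate 4 (0.204). Not run were the 75th percentile over all probes, which was -0.173 on P0 replicate 1, and the slide block, since all arrays share 1 slide. Low signal limits miR-497, miR-195, miR-208, miR-146a and miR-31, which lay at or near the floor at P0, and miR-126 on P0 replicate 1.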

Other observations

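The miRNAs in the first paragraph were chosen after their values were seen, while the tests of neighbouring genes and of hairpin arms in the second were set before their results were seen, and their repeats without undetected miRNAs after.

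Several miRNAs outside the lists had separate values at the 2 ages, as scaled and floored, without passing limma's adjusted threshold (Benjamini-Hochberg, n = 4 per age). miR-221, known for promoting cell division, was not well above background on any P0 array and was at least 2.41-fold higher at P10 (adjusted p = 0.132, limma), with log2 levels of -2.26 and -2.32 on P10 replicates 1 and 2 and -5.36 and -5.49 on replicates 3 and 4. miR-125b-5p differed by 1.37 ± 0.49 (SE) and miR-100 by 0.94 ± 0.34. In the rescaled fit without P0 replicate 1 miR-100 came to 0.45 ± 0.10 and passed (adjusted p = 0.0142, limma). So did miR-99b, miR-7a, miR-542-5p and miR-107 below in that fit. Without P10 replicates 1 and 2 miR-125b-5p came to 0.42. By contrast, miR-99b, in a cluster with miR-125a and let-7e, differed by -0.61 ± 0.20. miR-7a stood at 1.24 ± 0.38 and miR-101a at 0.68 ± 0.22, both at or near the floor at P0, against -0.89 ± 0.27 for miR-542-5p. miR-107, close in sequence to miR-103, differed by -0.82 ± 0.23 (adjusted p = 0.0626, limma), where miR-103 passed at -0.82. The values of miR-21 overlapped: it differed by 0.87 ± 0.61, with 4.58 and 4.61 on P10 replicates 1 and 2 but 2.21 on both others, inside the P0 range of 2.04 to 2.76, and by -0.32 without P10 replicates 1 and 2.

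miRNAs encoded near each other may change alike with age. Over 47 pairs of probes within 10000 bp in rn4, made of 49 miRNAs, the mean absolute difference between the log2 differences was 0.558, against 0.984 after permuting miRNAs (one-sided p = 0.00054, 100000 permutations). The sign was shared in 27 of 47 pairs. The largest differences were those of miR-199a-3p (2.57) and miR-199a-5p (2.23) with miR-214 (2.17), and of miR-497 (2.30) with miR-195 (2.12). The test was not repeated without them, so how far its result rests on them was not measured. The pair miR-23a (1.31) and miR-27a (0.93) went together, as did miR-30b-5p (-0.71) and miR-30d (-0.69), but miR-206 (1.05) and miR-133b (-0.02), 3879 bp apart, did not. The 2 arms of 1 hairpin may do so as well: over 17 hairpins the mean absolute difference was 0.566 against 1.16 after permutation (one-sided p = 0.00032, 100000 permutations), with the sign shared in 14. miR-378 (-0.91) and its star strand (-0.66) and miR-490 (-0.83) and its star strand (-0.93) were alike, while miR-328a (-0.59) and its star strand (0.56) were not. Without miRNAs that no P0 array detected, the one-sided permutation p was 0.00048 over 42 pairs of neighbours and 0.00049 over 15 hairpins. Pairs that share a miRNA are not independent, and both values rest on the same 8 arrays, P0 replicate 1 included.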
